A study of Mus musculus with 6 samples.

How the data were processed

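Medullary thymic epithelial cells (mTECs), the thymic cells that display proteins of other organs to developing T cells, were sorted from Mbd1 wild type and Mbd1 knockout mice 30 days old, per the labels' protocols. The gate kept live cells carrying EpCAM and MHC class II and excluded cells carrying CD45, CD11c or Ly51. RNA was amplified, labelled with Cy3 and hybridised to Agilent mouse arrays, 1 sample per array. Each genotype had 3 arrays; per the series' design text, 4 biological replicates per genotype were made and the authors removed 1 of each after quality control. Whether a replicate was 1 animal or a pool was not given in the sources used here. The labels and the design text gave no aim beyond the comparison of the genotypes.

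The deposited scanner files held intensity values per spot, on a linear scale, made with Agilent Feature Extraction (version 10.7.3.1 per the file headers and 10.6 per the submitters' processing notes). Per the file headers, the processed intensity was background-subtracted and detrended within the array, and nothing was normalized between arrays. The authors' deposited matrix held a log2 value per probe in 6 columns named wild type 1 to 3 and knockout 1 to 3; the tool was not given in the sources used here. The 6 columns shared nearly the same quartiles (medians 7.13 to 7.14) and the same maximum, the pattern quantile normalization leaves. In rank, 5 columns equalled the median spot intensity of a scanner file, without background subtraction, so folds of dim genes are understated on this scale. The matrix also held the authors' log2 ratio of knockout over wild type, the same as a linear fold, p-values (unadjusted and with 2 adjustments) and a log-odds score per probe. From the authors' deposited table only counts of probes and the values of Mbd1 were used, and the score was not used here.

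Each array had 43379 non-control spots of 41174 probes, none of them saturated. Between 72.6% and 79.4% of the probes were well above background, and 397 to 1306 spots per array were left out as outliers. Spots of the 245 replicated probes were averaged. Precision was limited by the number of arrays. A probe was kept where it was well above background on at least 3 of the 6 scanner arrays, whatever their titles, which left 32235 probes; the matrix carries no such flag, so the same probes were kept there. Probes were named through Entrez ID (32833 probes), accession (62) or the file's own symbol (2718), and 5561 had no symbol. Each gene was represented by its kept probe of highest mean over the 6 arrays. The build of the matrix's coordinates was not given in the sources used here, so chromosomes alone are printed.

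Before the data were examined, the groups, the fit, the gene lists, the rule for named genes and the processing alternatives were fixed. The fixed fit used the scanner files under their titles: log2 of the processed intensity (floor 1) minus the array's 75th percentile, then lmFit and eBayes of limma 3.58.1 in R 4.3.3 with a group term, and Benjamini-Hochberg adjustment over all genes (threshold 0.05). The authors' deposited matrix, grouped by its column names, was among the fixed alternatives and was fitted with the same model on its log2 values. The 2 sources gave opposite directions for Mbd1. Leading the account with the matrix columns was therefore chosen after the data were seen, and the fixed fit is reported after it. No scanner file was moved to another group.

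Gene lists were tested with limma's camera (preset correlation 0.01, two-sided), with an estimated correlation and with fry beside it, each adjusted over 27 lists with at least 5 measured members. The lists covered Aire-dependent antigens, Fezf2-dependent or Aire-independent antigens, antigens of 7 organ groups, keratinocyte terminal differentiation, the union of these, Aire partners, DNA methylation, imprinted genes, mTEC maturation, epithelial identity, 6 other cell types and 5 cell states. A list of 5 sex-linked genes served as a check only. Lists of plasma cell markers and of B cell markers other than immunoglobulin, and the set of immunoglobulin gene segments, were added after the data were seen. That set took probes described as immunoglobulin chains, entries of whole chains such as Igh-6 and Ighm included. By position it also took probes within the heavy or kappa chain span that had no description or were described as predicted or similar genes. Named genes were Mbd1, Aire, Atf7ip, Setdb1 and Fezf2, then up to 12 passing genes of largest change per direction without overlap between groups, skipping clone and accession names. A direction with fewer than 5 passing genes was filled to 10 by smallest p, and each list contributed up to 4 members of smallest p; 3 genes that this rule names are not reported here. With 3 arrays per group an exact permutation test cannot go below 0.1, so adjusted p-values from limma, which pools the spread over genes, were used.

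A probe at or under the 95th percentile of the never-detected probes in every column of a group was treated as a bound there. Alternatives were quantile or median centring, normexp background correction (offset 50, on median spot and median local background intensity), no filter or a filter on all 6 arrays, the mean over a gene's probes, trend and robust moderation, the replicate number as a block, single probes, other thresholds, other set tests and leaving out each array. The slide as a block and a fit without immunoglobulin segments were added after the data were seen.

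The fit was tested on simulated data, with 50 genes changed at each fold. For the matrix columns (21384 genes), 2% of genes changed 1.5-fold, 56% of those changed 2-fold and 100% of those changed 4-fold or 8-fold were recovered, with 8 false among 137 calls. For the scanner files (20391 genes), 0% were recovered at 1.5-fold and at 2-fold, 74% at 4-fold and 100% at 8-fold, with 13 false among 100 calls. A simulated shift of 1 list was found in both, and 0 other lists passed. The simulated genes varied independently of each other, so this does not test lists whose members move together. In the matrix columns the estimated correlation between members was 0.32 for proliferation genes and 0.15 for B cell markers. Figures were drawn with matplotlib 3.10.9.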

Results

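Gene expression was measured in sorted mTECs of Mbd1 wild type and Mbd1 knockout mice, 3 arrays per genotype. Mbd1 encodes a protein that binds methylated CpG sites in DNA, and Aire, the autoimmune regulator, drives expression of many tissue antigens in mTECs. The comparison addresses which genes, tissue antigens among them, differ in mTECs without Mbd1.

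In the authors' matrix, Mbd1 (chromosome 18) was low in all 3 columns named knockout and well expressed in all 3 named wild type. The probe A_51_P143224 read 8.83, 8.60 and 9.0 in columns wild type 1 to 3 and 5.64, 5.61 and 5.60 in columns knockout 1 to 3, on the log2 scale. The means were 8.81 ± 0.20 and 5.62 ± 0.02 (SD, n = 3), and the difference was -3.19 (SE 0.19, adjusted p = 5.4e-05). The other 2 Mbd1 probes differed by -2.96 (SE 0.16) and -0.98 (SE 0.16). The highest signals of probes never detected lay between 5.50 and 5.67 (95th percentile per column), and for each of the 3 probes 2 of the 3 knockout columns lay at or under that level, so the knockout columns were at or near background and the size of the fall is uncertain. The authors' deposited table gives -3.19 for the same probe, with an FDR of 5.9e-04. The part of the gene that was deleted is not given in the labels, so the place of the probes relative to it was not checked.

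The scanner files gave another picture under their titles. The same probe had a processed intensity of 20.9, 305 and 15.6 on the arrays titled wild type 1 to 3, the lowest of them not well above background. On the arrays titled knockout 1 to 3 it was 356, 17.2 and 682. Mbd1 was thus bright on 1 array titled wild type and on 2 titled knockout. The difference of the titled groups was 1.59 (SE 1.62, 95% interval -2.18 to 5.36, adjusted p = 0.985), opposite in sign to the matrix. It lay between 0.69 and 3.19 when an array was left out.

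**Figure D1:**
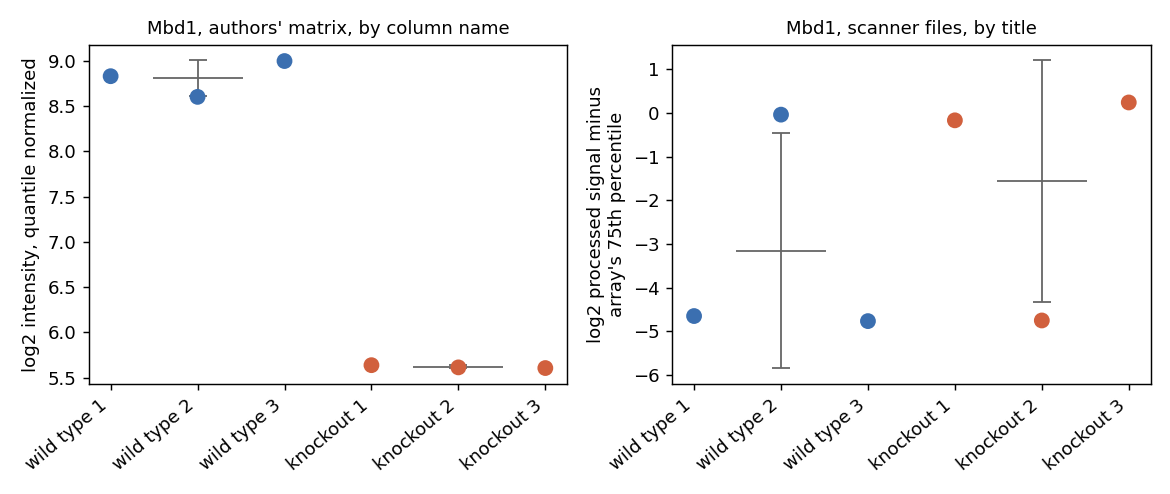
Mbd1 (probe A_51_P143224) in each sample, on the left as log2 intensity in the authors' matrix by column name and on the right as log2 processed intensity minus the array's 75th percentile by array title; lines show group means and bars the SD (n = 3). The knockout columns lie between 5.60 and 5.64 and the wild type columns between 8.60 and 9.0, whereas the titled arrays are mixed within each group.

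Matrix columns and scanner files were matched by rank over the probes with a single spot. Of the 6 columns, 5 equalled an array exactly (Spearman's rank correlation of 1 across probes), 0 of them the array of the same title and 4 an array titled with the other genotype. Column wild type 1 equalled the array titled wild type 2. Columns wild type 2 and wild type 3 equalled the arrays titled knockout 1 and knockout 3. Columns knockout 2 and knockout 3 equalled the arrays titled wild type 1 and wild type 3. Column knockout 1 equalled no array, and the array titled knockout 2 equalled no column. All other pairs had a rank correlation between 0.952 and 0.986. The genotype of a sample is therefore given below as the name of its matrix column or the title of its array, and every direction depends on which is right. Mbd1, the targeted gene, argues against reading some of the titles as genotypes. Its probe A_51_P143224 was dim on the arrays titled wild type 1 and 3 (processed intensity 20.9 and 15.6). It was bright on those titled knockout 1 and 3 (356 and 682).

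**Figure D2:**
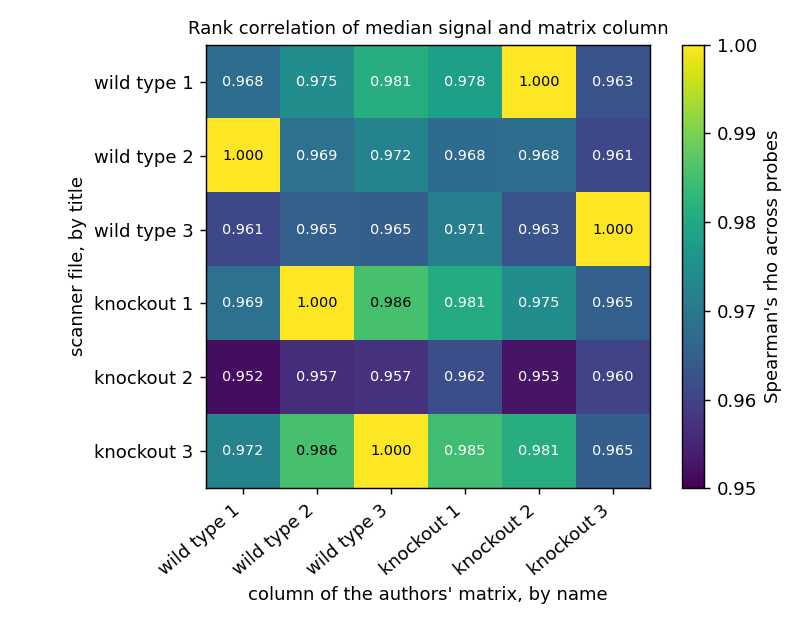
Spearman's rank correlation across probes with a single spot, between the median spot intensity of each scanner file (by title, vertical) and each column of the authors' matrix (by name, horizontal). The 5 pairs at 1 lie off the diagonal of equal titles, and all other pairs lie between 0.952 and 0.986.

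Between the matrix columns named knockout and wild type, the knockout columns had higher immunoglobulin transcripts and lower Mbd1 and Mrps35. Igkv9-120, a variable segment of the immunoglobulin kappa light chain on chromosome 6, had the largest change of the named genes, at 4.13 on the log2 scale (SE 0.30, adjusted p = 2.6e-04). Igh-6, the mu heavy chain, rose by 3.39 (SE 0.52, adjusted p = 0.031), and a probe of the heavy chain locus named Igh rose by 2.99 (SE 0.39, adjusted p = 0.011). Ighm, another entry of the mu heavy chain, read 2.49 and did not pass over all genes (limma, adjusted p = 0.123). Of 126 measured immunoglobulin segments, 18 passed over all genes, all of them higher, and 87 were higher adjusted over the list alone. Their median change was 1.74, 118 were positive, and the medians per column were 6.64, 6.89 and 6.95 in wild type and 7.97, 9.58 and 8.51 in knockout. In 79 segments every knockout column lay above every wild type column. In either direction 64.3% did not overlap, against 10% by chance for a single gene. The segments moved together (estimated correlation 0.355) and were set apart after the data were seen, so these counts are not independent support. For the set, camera with an estimated correlation gave p = 0.0101 and fry p = 0.0129, both unadjusted. Since the set was chosen from these same values, these p-values are not independent support either. Segments of this family are similar in sequence, so their probes can share transcripts and single members are uncertain. One segment, ENSMUST00000103481, picked after its values were seen, was at background in the wild type columns and at least 6.14-fold higher in the knockout columns (adjusted p = 5.4e-05). Igh-6 lost its call without column wild type 1 (adjusted p = 0.108), wild type 2 (0.169), knockout 1 (0.0578) or knockout 2 (0.0568), and Igh without wild type 1 (0.0632) or wild type 2 (0.0789). Processing settings also ended them: Igh-6 with no filter on dim probes (adjusted p = 0.188), the mean over probes (0.0613) or trend and robust moderation (0.0905), and Igh with no filter (0.0870) or detection on all 6 arrays (0.0909).

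**Figure D3:**
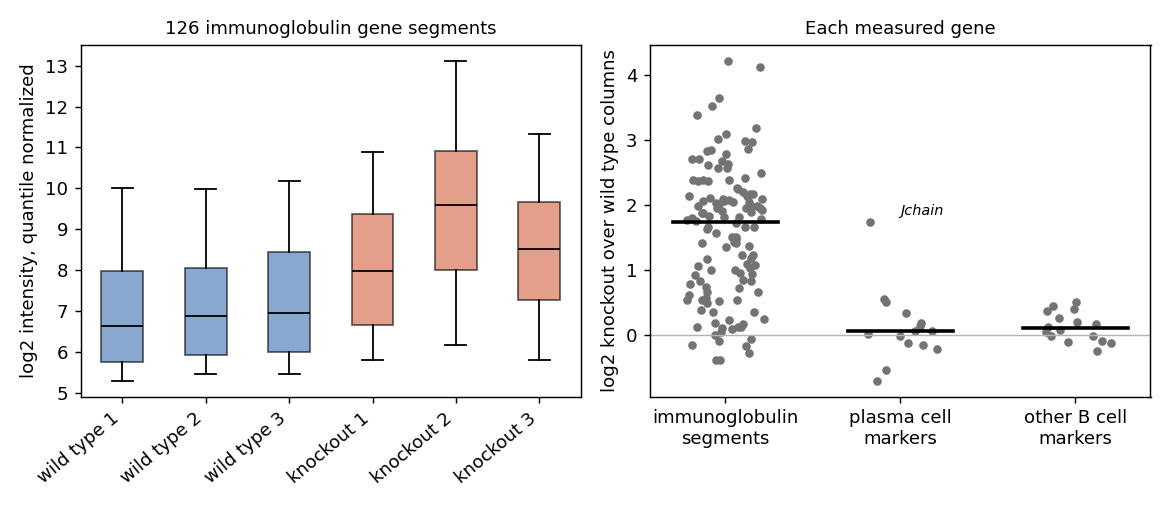
Left, log2 intensity of 126 immunoglobulin gene segments per matrix column (box, quartiles and median; whiskers, 5th to 95th percentile), with medians of 6.64 to 6.95 in the wild type and 7.97 to 9.58 in the knockout columns. Right, log2 knockout over wild type of each segment, plasma cell marker and other B cell marker (dots), with medians (bars) of 1.74, 0.06 and 0.10.

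Outside the immunoglobulins 14 genes passed, 12 higher and 2 lower in the knockout columns. Scgb2b27 and Scgb1b27, secretoglobins of the androgen-binding protein family on chromosome 7, rose by 2.11 (SE 0.21, adjusted p = 0.0015) and 2.06 (SE 0.26, adjusted p = 0.0091). Il22, a cytokine that acts on epithelial cells, rose by 2.06 (SE 0.22, adjusted p = 0.0028), and Dppa5a, a gene of pluripotent cells, by 1.94 (SE 0.18, adjusted p = 0.0013). Wfdc12 and Slpi, protease inhibitors of the whey acidic protein family on chromosome 2, rose by 1.75 (SE 0.20, adjusted p = 0.0061) and 1.52 (SE 0.22, adjusted p = 0.021). Coch, an extracellular matrix protein of the inner ear, rose by 1.65, and Cartpt, a neuropeptide precursor, by 1.44 (adjusted p of 0.0091 and 0.011). Mrps35, a protein of the small mitochondrial ribosomal subunit on chromosome 6, fell by 2.71 (SE 0.25, adjusted p = 0.0013), from 13.0 ± 0.22 in the wild type to 10.3 ± 0.48 in the knockout columns (SD, n = 3). Another Slpi probe read -0.18, and the mean over both Slpi probes was 0.67 (adjusted p = 0.361); with no filter on dim probes neither Slpi (adjusted p = 0.0611) nor Scgb1b27 (0.0575) passed. Slpi lost its call without column wild type 2 (adjusted p = 0.169), wild type 3 (0.159) or knockout 1 (0.0826), Scgb1b27 without wild type 2 (0.0632), Coch without wild type 3 (0.0612) and Cartpt without wild type 1 (0.0514) or wild type 2 (0.112).

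In total 32 of 21384 genes passed between the matrix columns, 30 higher and 2 lower, all at least 2-fold and without overlap, and 55 passed at an adjusted p of 0.1. At an unadjusted p of 0.05, 916 genes (4.28%) passed, and 8.37% of all genes did not overlap, against 10% by chance. The authors' deposited table lists 26 of 41174 probes with an FDR under 0.05, 23 higher and 3 lower. The count was 24 without column wild type 1, 16 without wild type 2, 24 without wild type 3, 50 without knockout 1, 29 without knockout 2 and 54 without knockout 3. With the slide as a block over the 5 columns with a known slide, 0 passed (smallest adjusted p = 0.0738; 1431 at an unadjusted p of 0.05), and Mbd1 read -3.22.

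Too few lower genes passed to fill that direction, and the next by p did not pass. Plcz1, the sperm phospholipase that activates the egg, read -1.95 (adjusted p = 0.065), and Hebp1, a heme-binding protein, read -1.23 (adjusted p = 0.086); both lie on chromosome 6. Apoc3, an apolipoprotein of the liver, read -1.01, Sis, the intestinal sucrase-isomaltase, -1.04, and Reg1, a secreted pancreatic protein, -0.90. Lrp1b, a lipoprotein receptor family member, read -1.03, Hddc3 -1.22, and Ube2e2, a ubiquitin-conjugating enzyme, -0.89, with 0.11 at its other probe. Plcz1 passed without column wild type 1 (-2.36, adjusted p = 0.00921) or knockout 3 (-2.10, 0.0420), with trend and robust moderation (0.0468) and with the replicate number as a block (0.0197), and Hebp1 (-1.43, 0.0202) and Hddc3 (-1.49, 0.0363) without knockout 3.

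**Figure D4:**
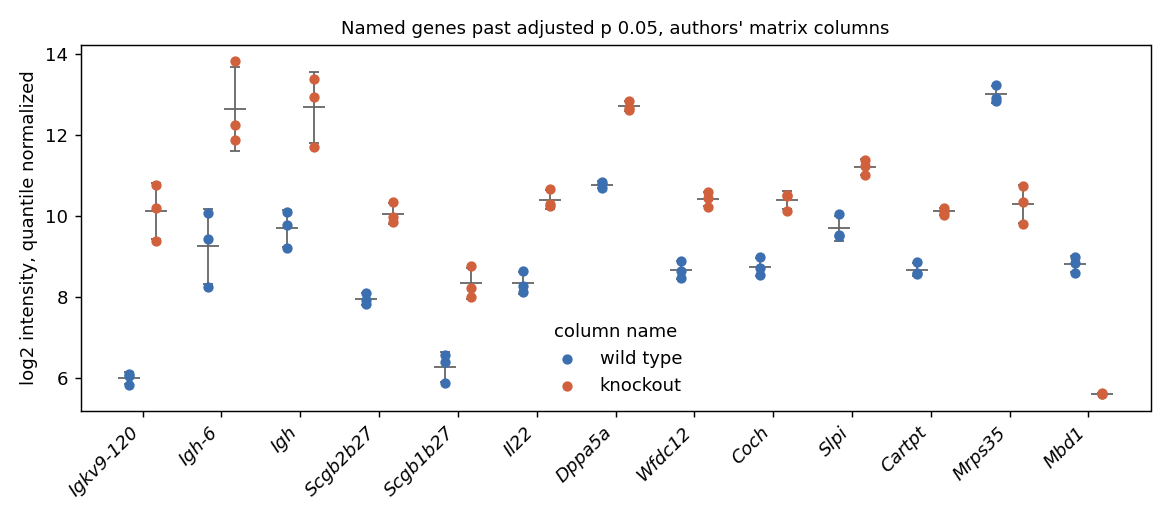
Log2 intensity in the authors' matrix of the named genes that passed an adjusted p of 0.05, each dot a column (wild type blue, knockout red), with lines for group means and bars for the SD (n = 3). The 11 higher genes stand left of Mrps35 and Mbd1, which fell by 2.71 and by 3.19.

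Aire itself and the proteins it works with, Mbd1 aside, did not pass between the matrix columns. Aire read 0.30 (SE 0.26, adjusted p = 0.999), and Fezf2, a second driver of tissue antigens in mTECs, -0.02 (SE 0.28). When a column was left out, Aire read between 0.11 and 0.58. Atf7ip, a partner of Mbd1, read 0.39 with its 4 probes between -0.19 and 0.39, and Setdb1, the histone methyltransferase bound by Atf7ip, 0.41. Of 37 measured Aire partners and regulators, Mbd1 alone passed, and Atf7ip, Daxx (0.41) and Relb (0.32) were next by p; 30 were positive, and the list, Mbd1 included, had a mean of 0.05 and a median of 0.15 (adjusted p = 0.0866). Of 35 genes of DNA methylation and heterochromatin, again Mbd1 alone passed, with Dnmt3l at -0.40, and the list had a mean of -0.07, a median of 0.07 and an adjusted p of 0.908.

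The Aire-dependent tissue antigens did not pass as a list in the knockout columns. Of 22 measured members, 4 were positive and 18 negative, with a mean of -0.08 and a median of -0.07 (adjusted p = 0.129, and adjusted p = 0.488 with an estimated correlation). None passed over all genes; adjusted over the list alone, 1 was higher and 1 lower. These were Svs2, a seminal vesicle protein, at 1.37 (SE 0.23, adjusted p = 0.062 over all genes), and Mucl2, a salivary protein, at -0.79 (SE 0.19). Ins2, insulin, read -0.69 and Bpifb9a -0.49. Without column wild type 1 the list passed as lower (mean -0.16, adjusted p = 0.0138), and without wild type 3 its mean was 0.00; with the slide as a block it was 0.03.

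The Fezf2-dependent or Aire-independent antigens were lower in the knockout columns, with 10 of 11 members negative and a mean of -0.34 (adjusted p = 4.0e-04). That call was lost with an estimated correlation (adjusted p = 0.372 with an estimated correlation) and with the slide as a block (mean -0.27, adjusted p = 0.209). Among its members of smallest p were Apoc3, the only one lower adjusted over the list alone, Ttr, the thyroxine carrier transthyretin (-0.52), and Krt10, a skin keratin (-0.46).

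Antigens grouped by organ gave no passing list, and 0 of their members passed over all genes. Adjusted over the list alone, Sis and Reg3b, an antimicrobial lectin (-1.15), were lower and Gkn2, a stomach protein (0.68), was higher among 30 intestine and stomach antigens (mean -0.12, adjusted p = 0.126). Among 31 germ cell antigens (mean 0.10, adjusted p = 0.103), the oocyte genes Oog1 (0.91) and Nlrp5 (0.94) were higher adjusted over the list alone, and the sperm gene Smcp read -0.66. The 28 liver antigens had a mean of -0.05 and a median of 0.01 (adjusted p = 0.492), with Apoc3 lower adjusted over the list alone, Tdo2 at -0.63 and Apoa4 at -0.61. The 29 pancreas antigens had a mean of -0.10 (adjusted p = 0.126), with 0 passing adjusted over the list alone and Iapp, the islet amyloid peptide, at -0.60. The 22 salivary, lacrimal and prostate antigens had a mean of -0.07 (adjusted p = 0.171); Svs2 and Mucl2 were the members passing adjusted over the list alone, and the amylase Amy1 read -0.54. The 31 nervous system and eye antigens (mean -0.03, adjusted p = 0.558) and the 33 muscle and cartilage antigens (mean 0.04, median -0.04, adjusted p = 0.544) had 0 members passing adjusted over the list alone. Dct, a melanin enzyme, read 0.53, the myosin Myh2 1.17 and the giant muscle protein Ttn 0.80. Among 29 genes of keratinocyte terminal differentiation 22 were negative (mean -0.14, adjusted p = 0.0501, and adjusted p = 0.387 with an estimated correlation), with Krt2 at 0.77, Klk7 at 0.70, Krt1 at -0.55 and Spink5 at -0.54; 0 passed adjusted over the list alone. All 237 tissue antigens together had a mean of -0.04 (adjusted p = 0.251), with 3 higher and 2 lower adjusted over the list alone.

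Markers of blood cells, which the gate against CD45 should remove, were higher in the knockout columns. Of 28 thymocyte and T cell markers 21 were positive, with a mean of 0.29 (adjusted p = 6.1e-05, and adjusted p = 0.372 with an estimated correlation). Adjusted over the list alone 4 were higher and 0 lower: Dntt, the terminal transferase of antigen receptor joining (0.91), Cd8b1 (0.97), Cd3e (0.84) and the lymphocyte GTPase Rhoh (0.97). The 18 B cell markers had a mean of 0.44 and a median of 0.14 (adjusted p = 0.0053, and adjusted p = 0.387 with an estimated correlation). Igh-6 and Ighm (2.49) were the 2 members higher adjusted over the list alone, while Spib read 0.41 and Blk 0.44. Igh-6 and Ighm both name the mu heavy chain, so that gene counts as 2 of the 18 and weighs on the mean accordingly. Without the immunoglobulin genes the other 16 had a mean of 0.12 (adjusted p = 0.129). Of 28 dendritic cell and macrophage markers 21 were positive (mean 0.15, adjusted p = 0.047, and adjusted p = 0.387 with an estimated correlation), with the chemokine receptor Ccr7 at 0.77, the adaptor Tyrobp at 0.70, Itgax, which encodes CD11c, at 0.47 and Mrc1 at -0.65; 0 passed adjusted over the list alone. Without column knockout 2 the T cell list no longer passed (0.21, adjusted p = 0.0712), nor did the B cell list (0.31, 0.203) or the dendritic cell list (0.11, 0.254), and without wild type 1 the B cell list (0.31, 0.0560) and the dendritic cell list (0.08, 0.20) were lost. The dendritic cell list was also lost with no filter on dim probes (adjusted p = 0.0506), detection on all 6 arrays (0.110) or the mean over probes (0.0569). With the slide as a block, a fit that rests on column wild type 1, the means were larger. They were 0.42 for the T cell, 0.77 for the B cell and 0.32 for the dendritic cell list.

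Proliferation genes were also higher in the knockout columns, 29 of 32 positive with a mean of 0.23 (adjusted p = 2.6e-04, and adjusted p = 0.474 with an estimated correlation). Birc5 (0.60), Plk1 (0.60), Ccnb1 (0.46) and Aurka (0.50), genes of mitosis, had the smallest p, and 0 passed adjusted over the list alone. The call was lost without column wild type 2 (0.08, adjusted p = 0.358), without knockout 2 (0.15, 0.203) and with the slide as a block (0.13, 0.637).

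The other 10 lists did not pass, and 0 of their members passed adjusted over the list alone. For the epithelium itself, 36 genes of mTEC maturation and antigen presentation had a mean of 0.04 and a median of -0.04 (adjusted p = 0.336), with the protease Ctsz at 0.86 and Ciita, the master regulator of MHC class II, at 0.35. The 29 genes of epithelial identity had a mean of -0.04 (adjusted p = 0.446; Hoxa3 0.52, Krt15 -0.46), and the 22 tuft cell markers -0.05 (adjusted p = 0.485; Pou2f3, the tuft cell transcription factor, 0.26). The 19 cortical thymic epithelial markers had a mean of 0.13 (adjusted p = 0.0914), with the thymic protease Prss16 at 0.52 and the chemokine Ccl25 at 0.43. The 28 fibroblast and endothelial markers had a mean of 0.08 (adjusted p = 0.167; Tie1 0.64). The 30 imprinted genes had a mean of 0.02 (adjusted p = 0.641; Dlk1 0.43, Ndn -0.42). The 31 interferon response genes had a mean of -0.07 (adjusted p = 0.182; Iigp1 -0.63), and the 29 immediate early and stress genes 0.09 (adjusted p = 0.143; Nr4a1 0.46). The 32 ribosomal protein genes had a mean of 0.10 (adjusted p = 0.0654; Rpl28 0.36), and the 30 genes of oxidative phosphorylation -0.05 (adjusted p = 0.336; Cycs -0.36). None of the 27 lists passed with an estimated correlation or with fry.

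**Figure D5:**
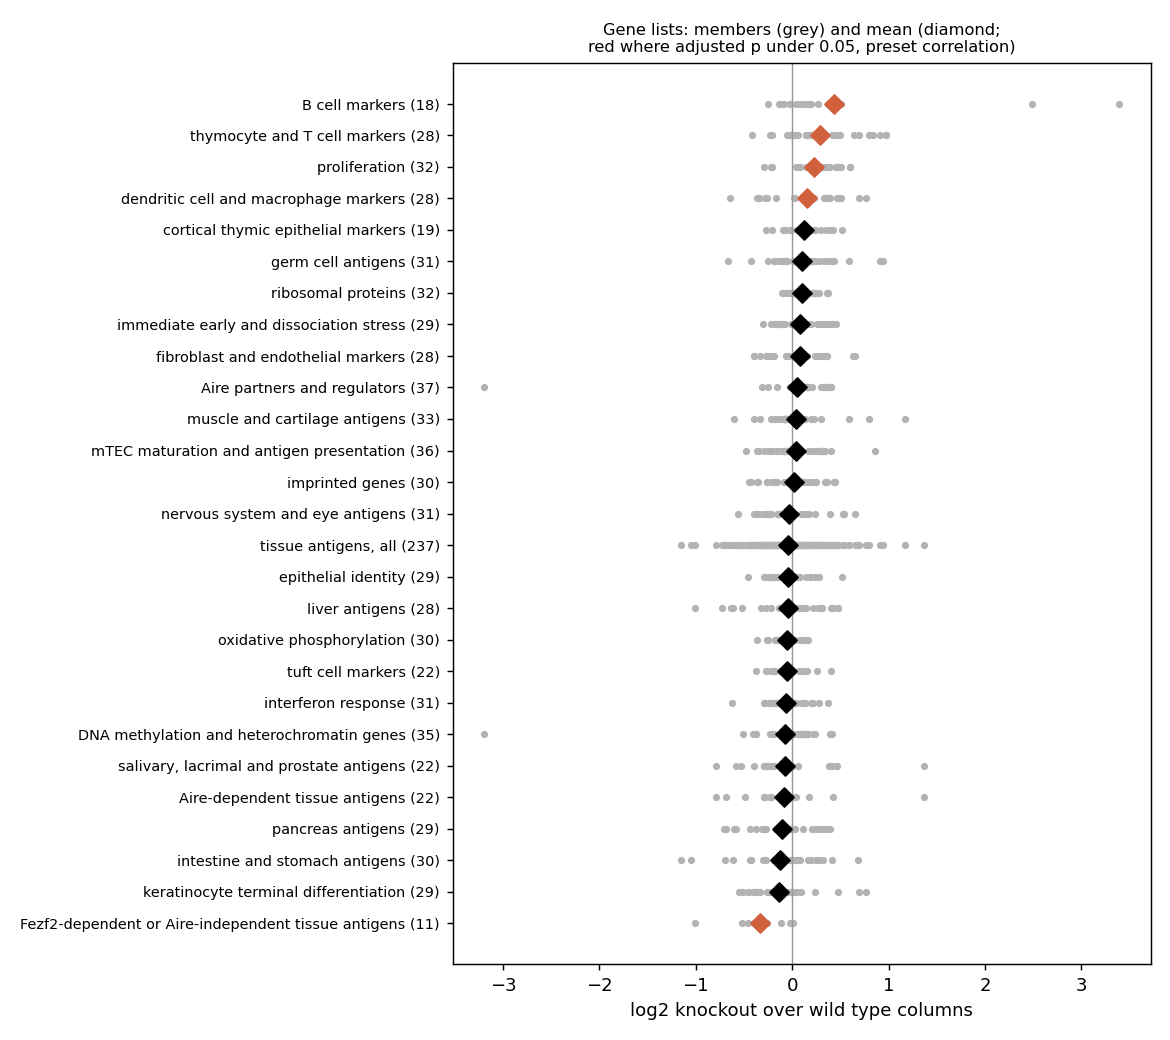
Log2 knockout over wild type in the authors' matrix for the measured members (grey dots, number in brackets) and mean (diamond) of each gene list, red where limma's camera with a preset correlation gave an adjusted p under 0.05. The B cell, T cell, proliferation and dendritic cell lists have means of 0.44, 0.29, 0.23 and 0.15, and the Fezf2-dependent or Aire-independent list has a mean of -0.34.

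Under the array titles, the comparison fixed before the data were examined, no gene could be called different between the titled groups. Each titled group held arrays with bright and with dim Mbd1, so this comparison could not test the genotypes. With limma, 0 of 21131 genes passed (smallest adjusted p = 0.985), and 902 (4.27%) had an unadjusted p under 0.05. Mbd1 read 1.59, against its knockout titles, so the directions here are those of titles and cannot be read as genotypes. Aire read 0.16, Atf7ip -0.33, Setdb1 0.00 and Fezf2 -0.09. Genes of smallest p on the higher side, none of which passed, included Wfdc6a (1.5), Mtg2 (1.34), the integrin Itgb3 (1.23), the transcription factor Sox6 (1.27), Zfp512b (1.27), Ftcd (1.13), Emilin1 (1.38), Arxes1 (1.09) and the odorant receptor Olfr610 (1.08). On the lower side they were Khdrbs2 (-1.11), Habp2 (-1.27), Tgfb1i1 (-1.16), the histone gene H4bc24 (-1.19), Pikfyve (-0.88), Abra (-3.29), Slc25a21 (-0.92), the immunoglobulin segment Igk-V38 (-2.75), Ptchd4 (-1.0) and Zfp518b (-1.15). Without the array titled wild type 1, 1 gene passed.

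Of the 27 lists, proliferation alone passed under the titles, lower on the arrays titled knockout (31 genes, mean -0.19, adjusted p = 2.5e-04, and adjusted p = 0.523 with an estimated correlation) and opposite to the matrix columns. That call was lost without the array titled wild type 1 or knockout 1, where 0 lists passed; 5 passed without knockout 2 and 2 without knockout 3. The median of all genes was 0.12 under this scaling, 0.14 after quantile normalization, 0.05 after median centring and 0.05 after normexp. Camera sets a list against all other genes, so lists with a mean above 0 but below that shift tested as lower, the B cell markers (0.07) and the interferon response genes (0.10) among them; the Aire partners had a mean of 0.06 and a median of -0.05. The 20 Aire-dependent antigens, 15 of them positive, had a mean of 0.24 (adjusted p = 0.248, and adjusted p = 0.523 with an estimated correlation). All arrays titled wild type lay on slide 1 and all titled knockout on slide 2, so slide and title cannot be told apart in this comparison.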

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

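The slide as a block and the fit without immunoglobulin segments were chosen after the data were seen; the other settings were planned. Between the matrix columns, all 32 passing genes that could be measured kept their direction in every setting fitted per gene; over single probes, 1 of the 2 kept Slpi probes read -0.18. Single named genes kept their side of the threshold in 273 fits, lost a call in 35, gained one in 6 and turned in 4, all 4 of Fezf2, which read between -0.36 and 0.20 when a column was left out and 0.17 with the slide block. The passing lists kept their call in 52 fits and lost it in 13. The count of 32 became 18 without a filter on dim probes, 57 over single probes, 55 at an adjusted p of 0.1, 13 without immunoglobulin segments and 0 with the slide block, where a single wild type column is left to set against 2 knockout columns on the same slide. Leaving out a column gave 16 (without wild type 2) to 54 (without knockout 3), with 50 without knockout 1. Requiring detection on all 6 arrays removed the bright Mbd1 probes, and the dim one read -0.98 (adjusted p = 0.12); with the slide block Mbd1 read -3.22 (adjusted p = 0.0738), and -3.30 to -3.10 when a column was left out. The Aire-dependent list read 0.028 with the slide block, and -0.16 (without wild type 1, adjusted p = 0.0138) to 0.0024 (without wild type 3) otherwise. Of the other lists 5 passed; this became 3 with the slide block, 0 with an estimated correlation, 0 with fry, and 2 (without knockout 2) to 10 (without wild type 1). The cause of these shifts was not tested.

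The replicate numbers do not pair the samples: same-numbered columns deviated with correlations of -0.28, -0.17 and -0.33, and same-numbered titles with -0.0048, -0.08 and -0.31. The fit with the replicate number as a block called 57 genes, 54 of them higher, of which 30 were among the 32; no column correlated best with its own number.

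Under the array titles, the count of 0 genes became 32 in the authors' matrix and 0 to 1 when an array was left out (1 without wild type 1). Mbd1 turned from 1.59 to -3.19 in the authors' matrix, and the Aire-dependent list from 0.24 to -0.085. The matrix also groups the samples otherwise: 4 of its 5 matched columns equal an array titled with the other genotype. Column knockout 1 and the array titled knockout 2 have no partner. Changes between the titled arrays and the matrix are thus changes of labels and samples as well as of processing. The 1 passing list became 4 with normexp, 2 without a filter, 5 in the authors' matrix, 0 with an estimated correlation, 0 with fry, and 0 (without wild type 1 or knockout 1) to 5 (without knockout 2). Of 25 named genes 3 kept their direction in the authors' matrix. The slide block could not be fitted, since each slide held 1 title. Dim genes were limited by signal over background, and 740 genes lacked a value on at least 1 array.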

Other observations

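The tests of the titles and of the matrix columns were chosen after the result was seen, the slide block and the plasma cell and other B cell lists were added after the data were seen, and the readings of their values by marker level and by columns per slide were set after those values were seen; the other tests were set before. Of the sex-linked genes, Xist lay between 12.1 and 13.4 in all 6 columns, and Ddx3y at 5.95 in column knockout 1 against 7.28 to 7.96 in the others. Kdm5d, Uty and Eif2s3y were also lowest in that column (5.34, 5.34 and 6.02), the first 2 under its background level of 5.64. Column knockout 1 thus differed from the others in Y-linked signal, and no fit accounted for sex. None of the 5 passed between the groups (limma, adjusted p = 0.999).

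Array titles and matrix column names disagreed. A mix-up of the matrix columns is argued against by Mbd1, whose lowest wild type column lay 2.97 above its highest knockout column on the log2 scale. A mix-up of the titles of the scanner files remains a candidate explanation: 0 columns equalled the array of their own title, where 5 equalled another, and Mbd1 followed the column names. By processed intensity, Mbd1 also argues against reading some titles as genotypes. The probe A_51_P143224 read 20.9 and 15.6 on the arrays titled wild type 1 and 3. On those titled knockout 1 and 3 it read 356 and 682. The arrays titled wild type 2 (305) and knockout 2 (17.2) read as their titles say. Which labels the submitters intended was not settled, since column knockout 1 and the array titled knockout 2 have no partner here.

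Immunoglobulin segments were higher in the knockout columns by a median of 1.74. The slide stays open: with it as a block over 5 columns the median was 1.99, the same as without it there, but slide 1 holds 1 wild type column and slide 2 holds 0 knockout columns, so that value rests on column wild type 1 (segment median 6.64, against 6.89 and 6.95 on slide 2) and the bound set for it was wrong. B cells carried through the sort stay open: the median of 16 other B cell markers was 0.10 (SD 0.23 across genes), but 14 of them have wild type levels above the segments' median of 6.81, a rough comparison of different probes, and a high level would hide a small share; the 8 below the median level of all genes, 8.07, had a median of 0.23 and a highest value of 0.50 (Cd22). Plasma cells carried through the sort stay open on the same ground: the median of 15 markers was 0.058, 11 lie above 6.81, and the 6 below 8.07 had a median of 0.11, with Jchain, which links secreted immunoglobulin, at 1.74 (adjusted p = 0.0404 over the list alone) and Mzb1 at 0.56 (0.0974), while the brighter Fkbp11 read -0.71 (0.0541) and Sec11c -0.55 (0.201). The bounds set for both types were thus wrong, the gate against CD45 should remove blood cells but how completely it did was not measured, and a change in the mTECs themselves was not tested.

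Genes lower in the knockout columns lay close together on chromosome 6, while Mbd1 lies on chromosome 18. Among 17589 placed genes, 79 were lower at an unadjusted p under 0.01, and 1 window of 51 neighbours held 6 of them: Dera (-0.60), Plcz1 (-1.95), Slco1a1 (-0.70), Iapp (-0.60), Arntl2 (-1.35) and Mrps35 (-2.71); 2 other genes in it were higher at the same threshold. Chance placing is argued against, since 0 of 1000 shuffled orders reached 6 (highest 5, 95th percentile 4), although neighbours can be regulated together. A sequence difference under single probes cannot be told apart from lower expression: 5 of the genes have 1 kept probe, and 0 of the 1 gene with another followed (Arntl2, -0.15). A segment of another strain on chromosome 6, which would not be linked to Mbd1, was not tested and may be a further explanation.

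The 6 matrix columns can be split in 10 ways, too few for a share under 0.05; the named split called 32 genes, the highest other split 2, and 1 of the 10 reached 32. The split that follows the matched slides, with wild type 1, knockout 2 and knockout 3 together, called 0. It places column knockout 1, whose slide is unknown, with the columns of slide 2. For the titled arrays the real split called 0 and the highest other 2. All 10 splits reached 0, which any split must, so this count decides nothing.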
